A study of Homo sapiens with 6 samples.

How the data were processed

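RNA was measured in MCF7 cells, a human breast cancer line that expresses the oestrogen receptor, exposed to medium conditioned by growing fibroblasts (3 libraries) or by senescent fibroblasts (3 libraries). Per the labels' protocols, cells were washed, RNA was taken up in Trizol, and 1 microgram of total RNA per library went into the Illumina TruSeq RNA kit. The labels give neither the dilution of the medium nor the time of exposure. They do not say whether the 3 replicates of a group came from separate cultures, so the p-values below may measure technical spread.

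The deposited table holds one row per gene symbol (56608 symbols) and one column per library, in a signal unit: read counts per gene that the authors divided by one size factor per library, with DESeq2 per the submitters' processing notes. Its name marks the counts as unstranded. The aligner, the counting tool, the genome build and the annotation are not given in the sources used here, so no coordinates are printed. Every value was a whole multiple of the value of 1 read in its column (100% of values, tolerance 1e-06 of a read), and whole reads were recovered from this. They summed to between 31642965 and 34603695 per growing-medium library and between 33440150 and 35122961 per senescent-medium library. No column was left unused, and 35248 symbols had a read in at least 1 library. Of all symbols, 97.0% matched a gene name in GENCODE release 29, and of those tested, 98.1%; this annotation was used only for gene types and overlapping exons. Because counting ignored strand, reads from a gene and a gene on the opposite strand over the same sequence cannot be told apart. In that annotation, 36 of the 103 named genes shared exon sequence with a gene on the opposite strand, such as PGR with PGR-AS1, TYMS with ENOSF1, TGM2 with RPRD1B and PARP9 with DTX3L, and 14 with a gene on their own strand, and their values are less certain. Near-identical genes, such as S100A7 and S100A7A, SAA2 and SAA1, AKR1C2 and AKR1C1, HLA genes, histones and ribosomal proteins with processed pseudogenes, may share or lose reads, and their values are uncertain.

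Deposited values are not counts, so the main test was limma (version 3.58.1, in R 4.3.3) on log2(value + 1), with a mean-variance trend in eBayes and no other factor, two-sided, over the 16748 genes with a mean of at least 10 normalized reads over the 6 libraries. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and every adjusted p of a gene comes from this test unless another tool is named. Fold changes are on the log2(value + 1) scale, senescent minus growing, which understates the change of low genes. Values are means ± SD of normalized reads over the 3 libraries of a group. Where a group had 0 reads, the fold is a lower bound against 3 reads over the group. Where it had 1 to 3 reads, the ratio of summed reads is given with a 95% Clopper-Pearson interval of the share of reads, adjusted for library size. Floors and intervals cover counting error only, since the reads carry no molecular identifiers.

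The rule for naming genes and the gene lists were fixed before the data were examined, and the rule took most named genes from the results. Named were the 10 genes with the largest rise and the 10 with the largest fall among called genes with a mean of at least 50 and no overlap between the groups, up to 3 tested members with the smallest p in each list, and ESR1, PGR, GREB1, TFF1, MKI67, CDKN1A, CDH1, VIM, IL6, CXCL8, SOCS3 and NFKBIA. Of the 10 with the largest fall, 9 are described. The 26 lists, written from textbook knowledge, covered responses to interleukin-6 and STAT3, to NF-kB and tumour necrosis factor, and to interferon, antigen presentation with interferon-gamma targets, oestrogen response, luminal identity, epithelial to mesenchymal transition, basal and stem-like markers, targets of transforming growth factor beta, growth factor and immediate early genes, proliferation, p53 targets, secreted factors of senescent cells, hypoxia and glycolysis, cholesterol synthesis, fatty acid synthesis, the integrated stress response, the unfolded protein response, heat shock, oxidative stress, aryl hydrocarbon receptor targets, Notch and Wnt targets, fibroblast markers, mitochondrially encoded genes, ribosomal proteins and histones. Members absent under their current symbol were looked up under older names, and CTGF, CYR61, AARS, WARS, GARS and the older histone names were matched in this way. Lists were tested with camera (limma) at a preset correlation of 0.01, two-sided and adjusted over the 26 lists, again with an estimated correlation, and with fry, which tests whether a list's genes move on balance one way without comparing them with other genes. Some lists share members; NF-kB and secreted factors share 9 written genes.

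Alternatives were pseudocounts of 0.5 and 8, no filter, a mean of at least 50, TMM rescaling, quantile normalization, no trend, array weights, the replicate number as a block, edgeR's quasi-likelihood test (version 4.0.16) and DESeq2 (version 1.42.0) on the recovered reads, and leaving out each library in turn. Scaling to RPM of the library totals, and counts of genes changed by at least 1 on the log2 scale, were added after the data had been seen. Libraries of a group were checked for duplicates by the spread of their recovered reads over genes with at least 20 reads, and the closest pair still had 3.56 times the variance that counting error alone gives. The tests were checked on simulated counts for this comparison over 16748 genes, with 200 genes changed. In these, limma called 58%, 90%, 100% and 100% of genes changed 1.5, 2, 4 and 10 times, and 7.45% of its calls were unchanged genes. For edgeR the shares were 58%, 90%, 100% and 100%, with 8.90% of calls on unchanged genes, and for DESeq2 54%, 88%, 100% and 100%, with 12.3%. As many simulated genes rose as fell, and limma was given the true scaling of the libraries. In the data 48.9% of genes were called, far more than were changed in the simulation. The simulated shares therefore need not hold for the real comparison.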

Results

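RNA sequencing compared MCF7 cells kept in medium conditioned by senescent fibroblasts with MCF7 cells kept in medium conditioned by growing fibroblasts, with 3 libraries in each group. MCF7 is a luminal breast cancer line that depends on oestrogen receptor signalling, and senescent fibroblasts are known to secrete cytokines, growth factors and proteases. The design asks which genes of the cancer cells differ between both media. Libraries held between 31642965 and 35122961 reads assigned to genes. Values are normalized reads, mean ± SD, n = 3 per group.

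In senescent-fibroblast medium LCN2, an iron-scavenging protein of innate defence, went from 1.59 ± 2.75 to 5334 ± 2646 (log2 change 11.38, SE 0.61, adjusted p = 1.54e-07). S100A9, a subunit of calprotectin, went from 13.3 ± 2.50 to 24278 ± 14046 (log2 change 10.51, SE 0.41, adjusted p = 1.77e-08). GREB1, a coregulator that the oestrogen receptor induces, fell from 33698 ± 893 to 310 ± 44.0 (log2 change −6.77, SE 0.09, adjusted p = 4.72e-12). PGR, the progesterone receptor, fell from 3356 ± 326 to 183 ± 61.9 (log2 change −4.23, SE 0.18, adjusted p = 3.84e-08).

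Of the 10 genes raised most, S100A8, the partner of S100A9 in calprotectin, had 3 reads over the growing-medium libraries and was 2756 times higher (95% counting interval 943 to 13366), at 2688 ± 1704. S100A7, psoriasin, rose from 1.68 ± 1.57 to 1633 ± 1133. CP, the copper-carrying ferroxidase ceruloplasmin, rose from 7.75 ± 3.28 to 2464 ± 850, and C3, the central complement component, from 27.0 ± 0.297 to 5945 ± 2674. EHF, an epithelial ETS transcription factor, was 412 times higher (interval 141 to 2002) against 3 reads. With no read in growing-fibroblast medium, BPIFA1, a secreted airway protein, was at least 460-fold higher, S100A7A at least 361-fold and SAA2, an acute-phase apolipoprotein, at least 171-fold. S100A7 with S100A7A, and SAA2 with SAA1, are close copies whose reads may be shared, and CP overlaps exons of HPS3 on the other strand. Senescent replicate 3 had the lowest value of its group for each of these 10 genes, such as 2351 for LCN2, 8357 for S100A9 and 2910 for C3. Each of its values lay above the growing-medium range, as the rule for naming these genes required.

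Among the genes lowered most, RAMP3, a partner protein of calcitonin-family receptors, fell from 1668 ± 151 to 8.74 ± 2.44 (log2 change −7.45, SE 0.18, adjusted p = 1.17e-09). KLK11, a secreted serine protease, had 181 ± 20.3 in growing-fibroblast medium and 1 read over the senescent-medium libraries, a ratio of 536 (95% counting interval 95.8 to 21215). HEY2, a Notch target and transcriptional repressor, fell from 953 ± 29.2 to 44.9 ± 15. SLC4A10, a bicarbonate transporter, fell from 179 ± 22.3 to 6.39 ± 1.45. PABPC4L, METTL7A and the non-coding transcripts AC103770.1 and AC105383.1 fell as well, with log2 changes of −4.88, −4.42, −5.03 and −4.25. SLC4A10 overlaps exons of TBR1 on its own strand, so its value is less certain. Replicate 3 of the senescent group was the highest of its group for AC103770.1 (83.5), PABPC4L (67.2), HEY2 (62.1), METTL7A (37.7) and AC105383.1 (7.13), and not for RAMP3 (9.17), KLK11, GREB1 (267) or SLC4A10 (6.11).

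**Figure D1:**
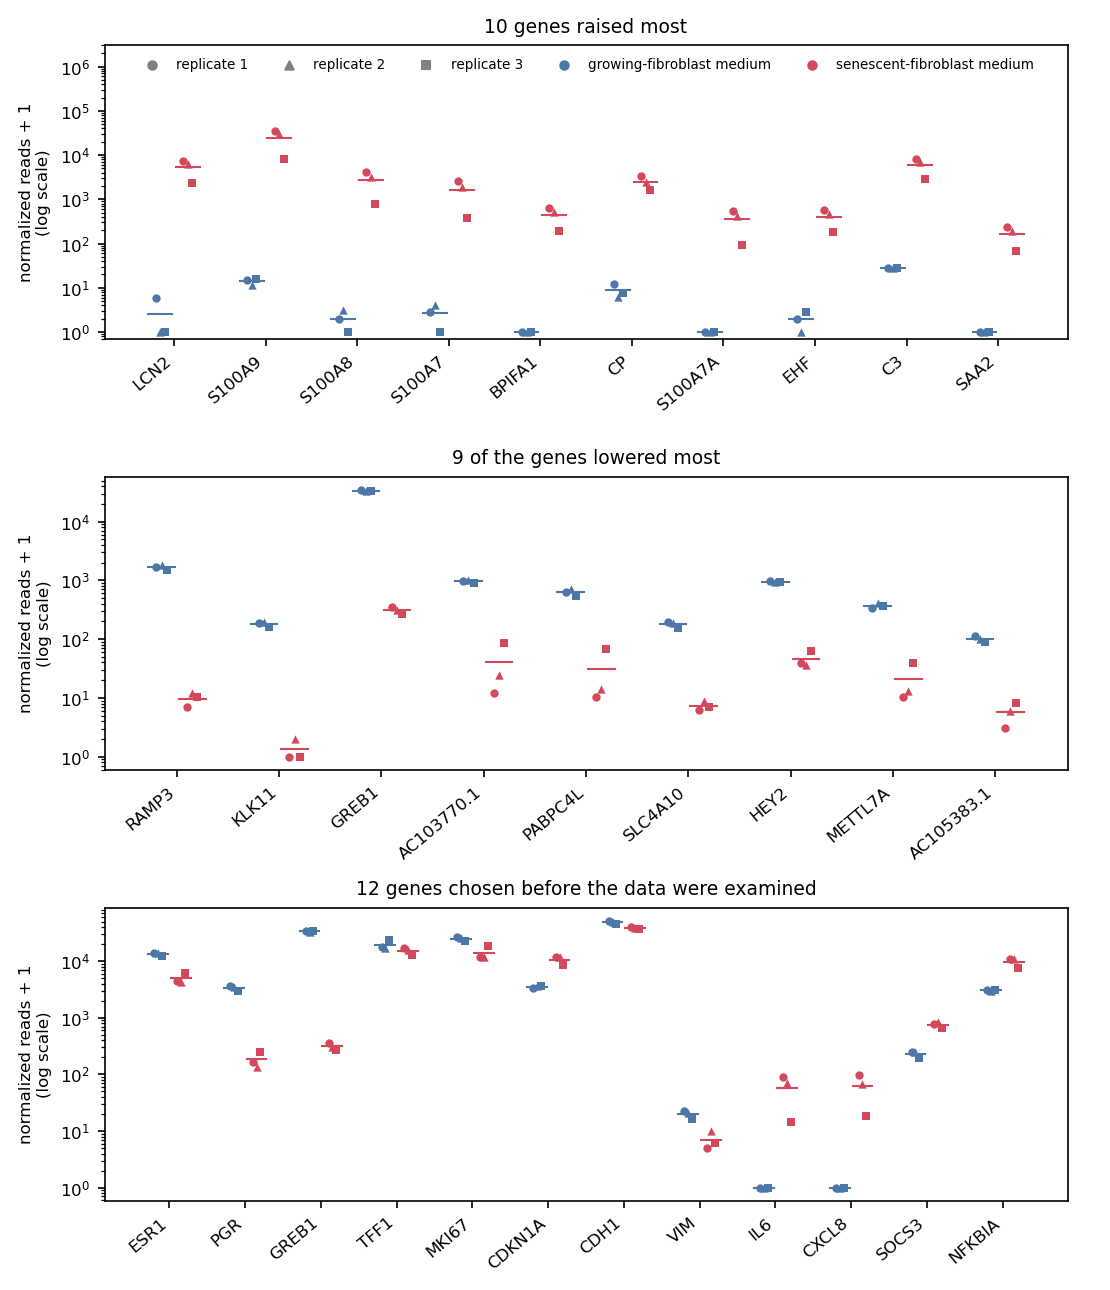
Normalized reads plus 1 (log axis) per library for the 10 genes raised most, 9 of those lowered most and 12 genes chosen before the data were examined; marker shapes give the replicate number and horizontal lines the group means. S100A9 had 13.3 in growing- and 24278 in senescent-fibroblast medium, GREB1 33698 and 310, and the square of senescent replicate 3 lies lowest of its group for all 10 raised genes.

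Across the 16748 genes tested, 4376 were higher and 3815 lower in senescent-fibroblast medium (limma, two-sided, adjusted p under 0.05), which is 48.9% of genes. A change of at least 1 on the log2 scale was found for 1088 higher and 712 lower genes. The groups did not overlap for 8041 of the 8191 called genes and for 9861 of all tested genes, where chance gives 10%. On recovered reads, edgeR called 4143 higher and 4028 lower and DESeq2 3968 and 3417, and limma shared 7940 calls in the same direction with edgeR and 7333 with DESeq2. Scaled to the library totals, 3459 were higher and 4910 lower, so which direction holds more calls depended on the scaling. Without senescent replicate 3 the counts were 4682 and 4302.

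Oestrogen-induced genes fell as a group. Of 30 tested members 27 fell, and the counts were the same adjusted over the list alone (camera adjusted p = 3.04e-16). RET, a receptor tyrosine kinase, fell from 5621 ± 367 to 547 ± 92.3 (log2 change −3.37) and IGFBP4, which binds insulin-like growth factors, from 15879 ± 477 to 4625 ± 17.6 (log2 change −1.78). Only AREG, a ligand of the epidermal growth factor receptor, and XBP1, a transcription factor, rose in this list (log2 changes 0.73 and 0.31), and CTSD did not pass (0.07). ESR1, the oestrogen receptor itself, fell from 13370 ± 1040 to 5016 ± 1119 (log2 change −1.43, SE 0.12, adjusted p = 4.39e-06). TFF1, a secreted trefoil protein and classic oestrogen target, had 19660 ± 3770 and 15205 ± 2231 (log2 change −0.36, SE 0.13, adjusted p = 0.0349) with overlapping groups. The TFF1 call was lost with DESeq2 (adjusted p = 0.117), with no variance trend (0.130), with the replicate number as a block (0.0653), without growing replicate 3 (0.148) and without senescent replicate 2 (0.0709). The list was also called with an estimated correlation (adjusted p = 0.0303), and its median change was −1.30, −1.29 and −1.05 in senescent replicates 1, 2 and 3.

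Luminal and epithelial identity genes moved both ways, 10 higher and 11 lower of 24, the same adjusted over the list alone, and the list was not called (camera adjusted p = 0.843). MUC1, a cell-surface mucin, rose from 2874 ± 59.9 to 9884 ± 1203, KRT7, a simple-epithelium keratin, from 137 ± 9.09 to 624 ± 96.1, and ELF3, an epithelial transcription factor, from 3271 ± 34.4 to 5985 ± 510. CDH1, the adhesion protein E-cadherin, fell from 48993 ± 3072 to 38753 ± 2148 (log2 change −0.34, SE 0.06, adjusted p = 0.00108). Among the 11 lower members were also GATA3, KRT8, KRT18, KRT19 and SPDEF (log2 changes −0.62, −0.60, −0.66, −0.36 and −0.88). Among the 10 higher members was FOXA1 (0.34). The list's median was −0.03 and its mean 0.10, so these differ in sign.

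Targets of interleukin-6 and STAT3 rose, 21 higher and 2 lower of 24 tested (camera adjusted p = 1.71e-09; adjusted p = 0.396 with an estimated correlation). Besides LCN2, BCL6, a transcriptional repressor, rose from 704 ± 20.9 to 1776 ± 91.7, and SOCS3, the feedback inhibitor of this pathway, from 232 ± 34.5 to 752 ± 89.5. CISH, another feedback inhibitor of cytokine receptors, fell from 517 ± 40 to 145 ± 8.90, and the kinase gene PIM1 fell as well (log2 change −0.46). NF-kB targets showed the highest list median (2.29), with 17 of 19 tested higher (camera adjusted p = 1.71e-09; adjusted p = 0.396 with an estimated correlation). BIRC3, an inhibitor of apoptosis, rose from 11.4 ± 1.00 to 840 ± 300, ZC3H12A, an RNase that degrades cytokine mRNAs, from 448 ± 27.8 to 4870 ± 1478, and RELB, an NF-kB subunit, from 76.7 ± 8.32 to 644 ± 121. NFKBIA, which encodes the inhibitor IkB-alpha, rose from 3089 ± 62.7 to 9851 ± 1884, and CD83 fell (log2 change −0.43). Of the 28 NF-kB targets written only 19 passed the filter. CXCL1, CXCL2, CXCL3 and CCL2 had means of at most 0.340 in both groups. IL1A had 6.32 and CCL20 0 in growing-fibroblast medium, and 1.35 and 7.05 in senescent-fibroblast medium. IL6 and CXCL8 passed the filter only through their senescent-medium values, which favours a high list median. Counts of both lists were the same adjusted over the list alone. In senescent replicates 1, 2 and 3 the median change was 1.38, 1.34 and 1.15 for STAT3 targets and 2.44, 2.52 and 1.90 for NF-kB targets.

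Secreted factors known from senescent cells were themselves higher in the exposed cancer cells, 13 of 16 tested, with IGFBP5 and SERPINE1 lower (log2 changes −3.15 and −2.39). The cytokine genes IL6 and CXCL8 had no read in any growing-medium library and reached 57.2 ± 39.5 and 60.6 ± 40.6, at least 58.5-fold and 61.9-fold higher; replicate 3 held 13.2 and 17.3, and IL6 overlaps exons of STEAP1B on the other strand. GDF15, a stress-induced cytokine, rose from 935 ± 178 to 6780 ± 2257, LIF, a cytokine of the interleukin-6 family, from 76.1 ± 11 to 495 ± 149, and IGFBP3 from 454 ± 29.3 to 1851 ± 287. The list passed with camera (adjusted p = 0.000164) and not with its correlation estimated (adjusted p = 0.396 with an estimated correlation), and the counts were the same adjusted over the list alone. Its median change was 1.62, 1.63 and 1.03 in senescent replicates 1, 2 and 3. Another 13 members lay under the filter and were not tested, among them PLAT at 0.632 ± 0.547 and 18.8 ± 13, CCL20 at 0 and 7.05 ± 5.29, IL1A at 6.32 ± 4.27 and 1.35 ± 0.596, and CXCL1, CXCL2, CXCL3, CCL2, CSF2, MMP3 and HGF with a mean of at most 0.340 in both groups.

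MHC class I presentation genes and interferon-gamma targets, written as 1 list, rose, 14 of 17 tested and 15 adjusted over the list alone, with none lower (camera adjusted p = 2.48e-07; adjusted p = 0.396 with an estimated correlation). TAP1 and TAP2, the subunits of the peptide transporter, rose from 156 ± 5.31 to 642 ± 58.6 and from 73.4 ± 13.2 to 365 ± 72.9, and TAPBP, which bridges it to MHC class I, from 1658 ± 32.5 to 4175 ± 519. Of 22 members written, CXCL10 (0 and 2.02), CD274 (0.950 and 3.36), CD74 (2.96 and 2.02), HLA-DRA (1.26 and 1.36) and PSMB8 (0.665 and 14.8) were not tested. These are means in growing- and then senescent-fibroblast medium. GBP1, PSMB9 and NLRC5 passed the filter only through their senescent-medium values, which favours a high list median. Interferon-stimulated genes were mixed, 13 higher, 2 lower and 8 not past the threshold of 23, the same adjusted over the list alone (camera adjusted p = 0.0110; adjusted p = 0.396 with an estimated correlation). PARP9 rose from 679 ± 23.5 to 2321 ± 184 and IFITM3, an antiviral membrane protein, from 1504 ± 40.5 to 3501 ± 655, while HERC6, an ISG15-ligase family member, fell from 365 ± 28.4 to 66.5 ± 12.9 and USP18, which removes ISG15, fell by 0.41 on the log2 scale. Of 30 interferon-stimulated genes written, IFI44, IFI44L, RSAD2 and XAF1 (means of at most 1.33 in both groups) were not tested. Nor were IFIT3 (3.25 and 11.5), MX2 (5.80 and 9.46) and OAS2 (1.90 and 2.71). IFIT1, IFIT2 and CMPK2 passed the filter only through their senescent-medium values. Senescent replicates 1, 2 and 3 had median changes of 1.38, 1.25 and 0.96 for the MHC class I list and 0.66, 0.53 and 0.43 for interferon-stimulated genes.

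Cell cycle genes of S, G2 and M phase fell, 35 of 37 tested, the same adjusted over the list alone (camera adjusted p = 6.50e-12; adjusted p = 0.396 with an estimated correlation). RAD51, the recombinase of DNA repair, fell from 1275 ± 70.6 to 584 ± 61.7, TYMS, thymidylate synthase, from 2041 ± 64.4 to 1085 ± 165, and CDC25C, a phosphatase of mitotic entry, from 1450 ± 32.2 to 709 ± 156. MKI67, the proliferation marker Ki-67, fell from 24935 ± 2137 to 14016 ± 3821 (log2 change −0.86, SE 0.14, adjusted p = 0.000538). CCNE1, the G1/S cyclin E1, rose by 0.40 on the log2 scale. The list's median change was −0.78, −0.68 and −0.33 in senescent replicates 1, 2 and 3.

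Genes induced by p53 rose, 20 of 24 tested and 21 adjusted over the list alone, with none lower (camera adjusted p = 4.20e-08; adjusted p = 0.0736 with an estimated correlation). CDKN1A, the cyclin-dependent kinase inhibitor p21, rose from 3509 ± 166 to 10684 ± 1852 (log2 change 1.59, SE 0.11, adjusted p = 7.45e-07). TP53INP1 rose from 1839 ± 67.7 to 6166 ± 986 and ZMAT3 from 968 ± 42.9 to 2044 ± 188. Unlike most lists, this one had its highest median change in senescent replicate 3 (0.73, against 0.59 and 0.66), and without that library 19 members were higher and 2 lower.

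Genes of the epithelial to mesenchymal transition rose in part, 10 higher and 4 lower of 17 tested (camera adjusted p = 0.00634; adjusted p = 0.417 with an estimated correlation). TGM2, a protein cross-linking enzyme, rose from 305 ± 31.3 to 3963 ± 197, FN1, fibronectin, from 3060 ± 75.1 to 19904 ± 4853, and LOXL2, a collagen cross-linking enzyme, from 187 ± 17.6 to 717 ± 139. Against the list's name fell VIM, the mesenchymal filament vimentin, which shares sequence with the antisense gene VIM-AS1, from 18.9 ± 3.51 to 6.04 ± 2.57 (log2 change −1.54, SE 0.35, adjusted p = 0.00394), the transcription factor gene SNAI1 (−0.92), S100A4 (−0.85) and L1CAM (−0.41). Basal and stem-like markers also rose in part, 8 higher and 3 lower of 14 (camera adjusted p = 0.0127; adjusted p = 0.396 with an estimated correlation). SOX9, a transcription factor of progenitor cells, went from 339 ± 2.79 to 1664 ± 58.3, ALDH1A3, a retinaldehyde dehydrogenase, from 79.3 ± 8.98 to 644 ± 55.3, and LAMC2, a basement-membrane laminin chain, from 245 ± 19.1 to 1682 ± 455, while NGFR, ITGB4 and KRT15 fell. Counts of both lists were the same adjusted over the list alone. In senescent replicates 1, 2 and 3 the median change was 1.17, 1.15 and 0.38 for the transition genes and 0.78, 0.94 and 0.42 for basal markers. Of 24 transition genes written, CDH2, ZEB2, TWIST1, MMP2 and TNC were among those under the filter, with means of at most 1.57 in both groups. Of 20 basal markers written, KRT5, KRT14 and ALDH1A1 (means of at most 1.29) were not tested. Nor were KRT6A (1.67 and 4.38), KRT17 (1.64 and 6.74) and PROM1 (1.30 and 4.06), in growing- and then senescent-fibroblast medium.

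Targets of transforming growth factor beta went both ways, 11 higher and 7 lower of 23 (camera adjusted p = 0.267), with BHLHE40, a transcription factor, at 614 ± 40.3 and 2907 ± 515, and the inhibitor of differentiation ID1 at 2304 ± 238 and 5062 ± 381, both raised. BAMBI, a decoy receptor of this pathway, rose from 2887 ± 168 to 5484 ± 281. With fry, the targets of this pathway moved up on balance (adjusted p = 0.00417). Fibroblast markers, included because fibroblasts made the medium, were 4 higher and 10 lower of 16 and not called (camera adjusted p = 0.182), with a median of −0.57 and a mean of 0.08 that differ in sign. The matrix genes FBN1 and COL5A2 rose from 165 ± 12.8 to 1853 ± 449 and from 194 ± 19.5 to 1779 ± 616, as did LUM and ACTA2 (log2 changes 1.82 and 1.06), while COL5A1 fell from 1516 ± 239 to 751 ± 127. Growth factor and immediate early genes rose, 15 higher and 5 lower of 26, and 16 and 5 adjusted over the list alone (camera adjusted p = 0.00501; adjusted p = 0.396 with an estimated correlation). PHLDA1 rose from 1130 ± 87.1 to 5001 ± 1052 and DUSP4, a phosphatase that inactivates MAP kinases, from 2686 ± 151 to 12722 ± 3326. The members that fell were EGR3, from 954 ± 46.3 to 150 ± 9.70, FOS, MYC, CCND1 and DUSP5. For this list the median change was 0.77, 0.92 and 0.61 in senescent replicates 1, 2 and 3. The counts of the other 2 lists were the same adjusted over the list alone.

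**Figure D2:**
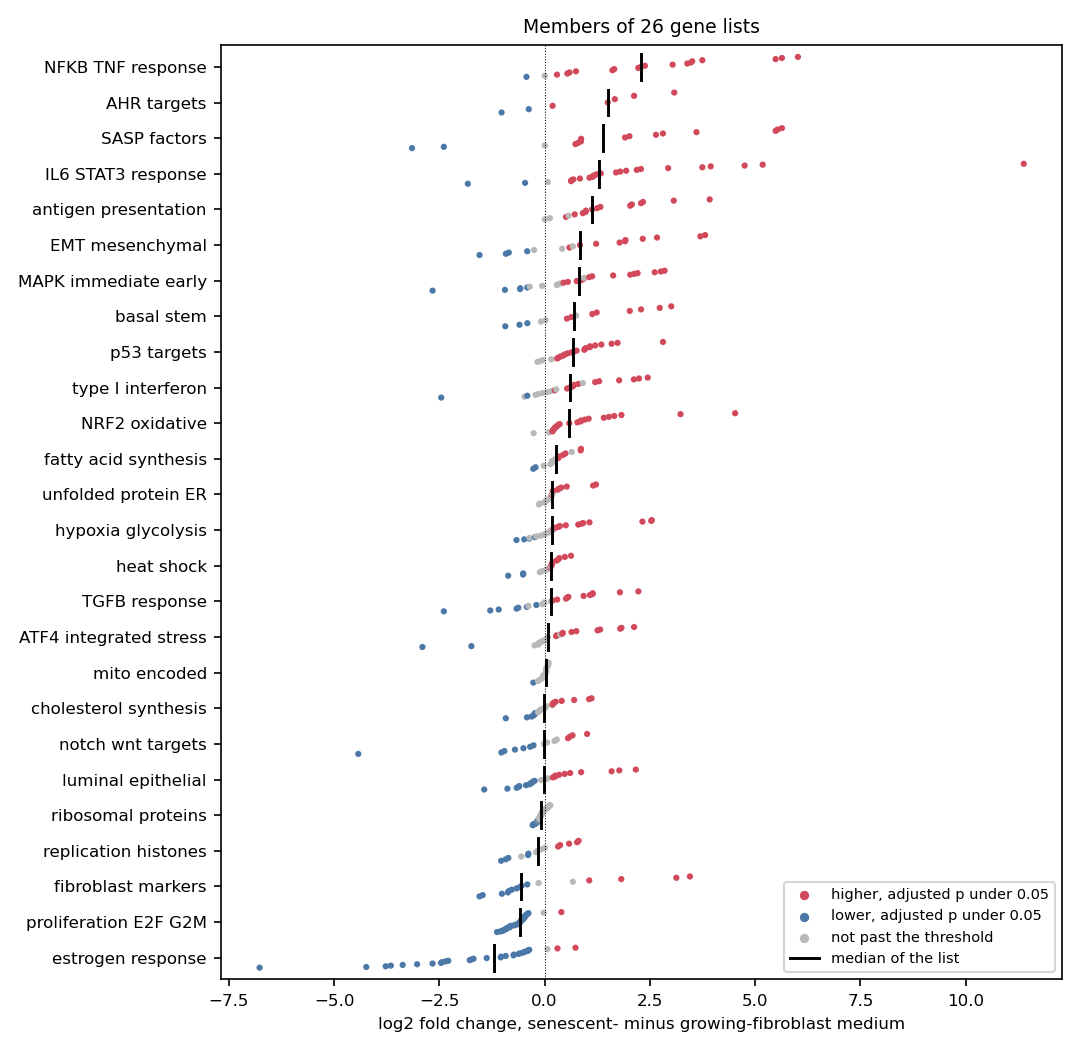
Log2 fold change (senescent- minus growing-fibroblast medium) of each tested member of the 26 lists, coloured by call, with the median of each list as a black bar. The medians run from −1.21 for oestrogen-induced genes to 2.29 for NF-kB targets, and several lists, such as luminal genes with a median of −0.03, hold called members on both sides of 0.

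Oxidative stress genes under NRF2 rose, 21 of 23 tested with none lower, the same adjusted over the list alone (camera adjusted p = 6.13e-08; adjusted p = 0.396 with an estimated correlation). TXNRD1, thioredoxin reductase, rose from 8152 ± 326 to 25869 ± 4288, SLC7A11, the cystine importer, from 575 ± 98.2 to 2025 ± 202, and AKR1C2, a steroid-reducing enzyme, from 681 ± 36.1 to 1812 ± 201. Their median change was 0.51, 0.75 and 0.50 in senescent replicates 1, 2 and 3. Endoplasmic reticulum genes were 8 higher, none lower and 12 not past the threshold of 20, the same adjusted over the list alone (camera adjusted p = 0.00913; adjusted p = 0.396 with an estimated correlation). CREB3L2 rose from 2153 ± 173 to 5017 ± 400, the co-chaperone gene DNAJC3 from 1527 ± 48.9 to 3403 ± 311, and EDEM1, which acts in the degradation of misfolded proteins, from 1787 ± 115 to 2575 ± 186. Here the median change was 0.20, 0.22 and 0.10.

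Amino acid and integrated stress response genes were 11 higher and 2 lower of 25, the same adjusted over the list alone (median log2 change 0.08, camera adjusted p = 0.0421; adjusted p = 0.484 with an estimated correlation). SLC7A5, a transporter of large neutral amino acids, rose from 8759 ± 820 to 38574 ± 7169, while STC2, a secreted glycoprotein, fell from 26910 ± 1216 to 8201 ± 1940 and NUPR1 fell by 2.90 on the log2 scale. This list call was lost with quantile normalization (adjusted p = 0.0527), with no variance trend (0.0575), with the replicate number as a block (0.0656), without growing replicate 1 (0.0729) and without senescent replicate 2 (0.0627), and its median was −0.00306 when scaled to library totals. Leaving out single libraries gave medians from 0.0499 to 0.213 for this list. Heat shock genes were 10 higher and 3 lower of 18, the same adjusted over the list alone, and not called (camera adjusted p = 0.208), though called up with fry (0.0129). The 3 that fell had the smallest p: FKBP4, a co-chaperone of steroid receptors, from 21921 ± 162 to 15422 ± 410, HSPB1, a small heat shock protein, from 47400 ± 4264 to 26068 ± 3109, and BAG3, a co-chaperone, from 6487 ± 89.6 to 4553 ± 227.

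Hypoxia and glycolysis genes were higher for 12 and lower for 4 of 28, and for 15 and 4 adjusted over the list alone (camera adjusted p = 0.0186; adjusted p = 0.396 with an estimated correlation). EGLN3, an oxygen-sensing prolyl hydroxylase, rose from 1082 ± 31.5 to 6326 ± 1060, ANGPTL4, a lipoprotein lipase inhibitor, from 128 ± 17.0 to 777 ± 237, and NDRG1 from 895 ± 67.6 to 1874 ± 165, while SLC2A1, the glucose transporter GLUT1, MXI1, ENO2 and KDM3A fell. Fatty acid synthesis genes were higher for 6 and lower for 2 of 14, and for 8 and 2 adjusted over the list alone (camera adjusted p = 0.0200; adjusted p = 0.396 with an estimated correlation). ME1, malic enzyme, rose from 2419 ± 130 to 4411 ± 348, FADS1, a fatty acid desaturase, from 6139 ± 109 to 8655 ± 260, and ACSL3, an acyl-CoA synthetase, from 7256 ± 233 to 13296 ± 2462, while FADS2 and ELOVL6 fell. Without senescent replicate 3, 10 fatty acid synthesis genes were higher; in senescent replicates 1, 2 and 3 that list's median change was 0.40, 0.32 and 0.14, and it was 0.19, 0.21 and 0.15 for hypoxia genes. Cholesterol synthesis genes split into 8 higher and 7 lower of 24, and 8 and 8 adjusted over the list alone, and were not called (camera adjusted p = 0.940), with a median of −0.00769 and a mean of 0.0523. The members with the smallest p rose, DHCR24 from 12328 ± 151 to 25712 ± 2670, MSMO1 from 1718 ± 89.0 to 3787 ± 900 and SC5D from 846 ± 20.2 to 1383 ± 169, whereas HSD17B7 fell (log2 change −0.42) and EBP, CYP51A1, DHCR7 and LSS did not pass (−0.14, −0.11, −0.09 and 0.02). The median was 0.0420 without senescent replicate 3.

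Aryl hydrocarbon receptor targets were 5 higher and 2 lower of 7 and not called (camera adjusted p = 0.0704), though called with no filter on low values (0.00434), with quantile normalization (0.0442), without senescent replicate 3 (0.0454), when scaled to library totals (0.0388) and with fry (0.00296). CYP1A1, a xenobiotic-metabolizing oxidase, rose from 37.8 ± 10.8 to 325 ± 79.1, while TIPARP, a feedback repressor of the receptor, fell from 1546 ± 96.8 to 760 ± 12.6, and AHRR fell too (log2 change −0.38). Notch and Wnt targets were 4 higher and 7 lower of 15 and not called (camera adjusted p = 0.341), though called down with fry (0.00704). Beside the fall of HEY2, the Notch target HES1 rose from 1485 ± 135 to 2243 ± 151, and DKK1, a secreted Wnt inhibitor, fell from 6313 ± 36.6 to 4980 ± 142. The median of the Notch and Wnt list was −0.0165, and 0.0152 without senescent replicate 3. Counts of both lists were the same adjusted over the list alone.

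Ribosomal protein genes were lower for 18 of 66 tested and for 6 adjusted over the list alone, by small amounts (median log2 change −0.09, camera adjusted p = 0.00950; adjusted p = 0.621 with an estimated correlation). RPL13A had 29905 ± 1392 and 24582 ± 499, RPS29 9173 ± 274 and 7582 ± 445, and RPS25 9244 ± 239 and 7666 ± 546 in growing- and senescent-fibroblast medium. The list was not called without growing replicate 3 (adjusted p = 0.0624) or with fry (0.0977). Of the 13 genes of the mitochondrial genome that encode proteins, MT-CO1 alone passed, also adjusted over the list alone, falling from 134735 ± 8790 to 111764 ± 2513, and the list was not called (camera adjusted p = 0.843; median 0.0352 and mean −0.0149). MT-CYB had 110082 ± 3241 and 103144 ± 2402 (adjusted p = 0.146), called with quantile normalization (0.00113) and when scaled to library totals (0.0131), and MT-ATP8 had 15454 ± 1055 and 13939 ± 1936 (0.189), called without senescent replicate 3 (0.0308), when 2 of the 13 genes were lower. Replication-dependent histones, whose mRNAs mostly lack a poly(A) tail, were 5 higher and 5 lower of 15, the same adjusted over the list alone, and not called (camera adjusted p = 0.590). Whether the counted transcripts carried a tail was not tested. HIST2H2BE had 3273 ± 84.7 and 5905 ± 1709, HIST1H2BC 154 ± 26.2 and 265 ± 58.1, both raised, and HIST1H1D 57.2 ± 6.88 and 31.4 ± 6.77, lowered.

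**Figure D3:**
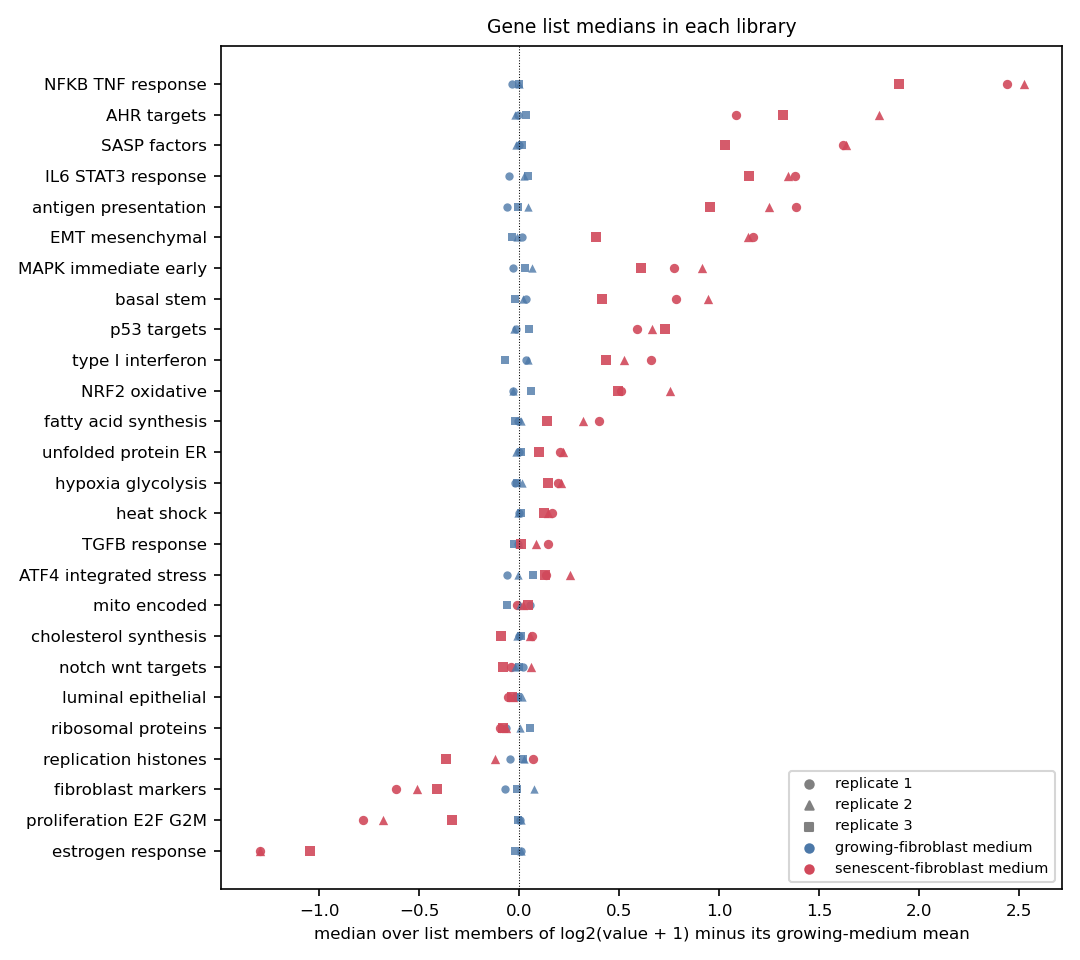
Median over each list's tested members of log2(value + 1) minus the member's mean in growing-fibroblast medium, for each of the 6 libraries; shapes give the replicate number. Senescent replicate 3 lies nearer to 0 than replicates 1 and 2 for NF-kB targets (1.90 against 2.44 and 2.52) and proliferation genes (−0.33 against −0.78 and −0.68), and not for p53 targets (0.73 against 0.59 and 0.66).

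Camera called 14 of the 26 lists higher and 3 lower, and of these 17 calls 16 were lost with an estimated correlation, the oestrogen list being the exception. With fry, 17 lists moved up and 3 down on balance. Seen over the first principal component of all tested genes, which held 84.6% of the variance, the growing-medium libraries lay at −53.4, −54.6 and −51.9 and senescent replicates 1, 2 and 3 at 64.9, 59.5 and 35.5.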

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

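Between 3558 and 4682 genes were higher and between 2836 and 4302 lower when each library was left out in turn, and between 3459 and 5140 higher and 3291 and 4910 lower under the other settings, all within 1.5 times of 4376 and 3815. Genes lower by at least 1 on the log2 scale numbered 408 with a mean of at least 50, against 712, since fewer genes (13083) were tested. Lists called were 0 higher and 1 lower with an estimated correlation, against 14 and 3 with the preset of 0.01. The estimates were 0.716 for cell cycle genes, 0.447 for STAT3 targets, 0.418 for NF-kB targets and 0.386 for oxidative stress genes. Calls of these lists thus rested on the preset. With an estimate, camera also tests on the few residual degrees of freedom of the 6 libraries, so lost calls do not reflect correlation alone. For the oestrogen list, with an estimate near the preset (0.0132), camera's unadjusted p went from 1.17e-17 to 0.00117, and the call was kept. For the p53 list (0.0174) it went from 8.08e-09 to 0.00566, and the call was lost. Under the other settings but fry, 13 to 15 lists were higher and 2 to 3 lower. The replicate number as a block gave 4360 higher and 3786 lower genes. Libraries with the same number showed little shared deviation from their group means (correlation across genes 0.105, 0.000225 and −0.0288). Unlike numbers from both groups gave −0.0913 to 0.0914. These correlations cannot exclude a pairing. Within a group, deviations from the mean of 3 libraries correlate negatively by construction, at −0.511 to −0.492 among growing-medium libraries. The values of senescent replicate 3 with replicates 1 and 2 (−0.695 and −0.528) therefore tell nothing about a pairing. Besides TFF1 and the integrated stress list, the block ended no call of a named gene or list. Lists with a median near 0 changed sign, and the cause was not tested: cholesterol synthesis 0.0348 with array weights (−0.0207 to 0.0420 leaving out single libraries), integrated stress −0.00306 when scaled to library totals, Notch and Wnt 0.0600 with no filter, 0.0217 with a mean of at least 50 and 0.0310 with array weights (−0.0535 to 0.0152 leaving out single libraries), mitochondrial genes −0.0485 with quantile normalization and −0.0446 when scaled to library totals (−0.00244 to 0.0477 leaving out single libraries), and histones 0.00461 with a mean of at least 50. Of the other comparisons of named genes with an alternative, 1842 kept their direction and side of the threshold, 3 gained a call (MT-CYB and MT-ATP8) and 5 lost it (TFF1). At this depth, values under about 1 normalized read per library (0.979 and 1.01 for 3 reads over a group) cannot be told from 0. Scaling to library totals was chosen after the data had been seen.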

Other observations

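Genes were also grouped by the letters that open their symbols, and all 249 families of at least 8 tested genes with at least 3 such letters were tested with camera; values are mean ± SD, n = 3 per group, in growing- and then senescent-fibroblast medium. Adjusted over the 249, the SEC, MCM and PSMB families were called, and none was with an estimated correlation (adjusted p = 0.964 for each family of this paragraph). Of 28 SEC genes, many of which encode the translocon and the coats of vesicles leaving the endoplasmic reticulum, 18 were higher and 1, SEC14L5, lower (adjusted p = 0.0102), with SEC24D at 2115 ± 68.6 and 3833 ± 192 and SEC24A at 2786 ± 93.4 and 5040 ± 746. Of 11 MCM genes 9 were lower and 0 higher (adjusted p = 0.0102), 6 of them on the cell cycle list of the report. All 9 PSMB genes, which encode beta subunits of the proteasome, were higher (median log2 change 0.34, adjusted p = 0.0200), the immunoproteasome subunit PSMB9 at 3.21 ± 2.11 and 32.3 ± 7.67 and PSMB5 at 10881 ± 729 and 14409 ± 1088. Families named below for their members were not called: TNFRSF, 9 higher and 2 lower of 13 (adjusted p = 0.0611; 0.0241 with quantile normalization, 0.0169 when scaled to library totals and 0.0266 without senescent replicate 3), COL, 4 higher and 16 lower of 32 (0.182), MUC, 7 higher and 1 lower of 10 (0.188), and TMED, 6 higher and 1 lower of 10 (0.226). In senescent replicates 1, 2 and 3 the median change was 0.40, 0.35 and 0.21 for SEC genes, −0.60, −0.57 and −0.29 for MCM genes and 0.32, 0.41 and 0.29 for PSMB genes.

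Single genes of these uncalled families stood out: MUC5B had 3930 ± 539 and 12631 ± 2612, MUC5AC 357 ± 21.6 and 1241 ± 413, and TNFRSF21 1959 ± 50.6 and 7852 ± 1294, all raised, whereas MUC16 fell from 317 ± 16 to 28.7 ± 13.5. COL27A1, COL4A5, COL4A6 and COL5A2 were the collagen genes raised. Other groups were put together by hand after their values had been seen and adjusted over 11 such groups, so their p is too favourable and is no independent evidence. The 11 also held groups of SEC, PSMB, TNFRSF, COL, MUC and TMED genes, and all 6 passed there (camera adjusted p = 0.000246, 0.00132, 0.00590, 0.0250, 0.0250 and 0.0250; adjusted p = 0.258, 0.278, 0.258, 0.258, 0.278 and 0.278 with an estimated correlation), COL not with quantile normalization (0.0764) or when scaled to library totals (0.0773). SERPIN genes, a family of protease inhibitors, were higher for 12 of 16 and lower for SERPINE1 (camera adjusted p = 0.00145; adjusted p = 0.258 with an estimated correlation), with SERPINA3, an acute-phase protein, at 11.1 ± 2.18 and 189 ± 54.4 and SERPINE2 at 89.6 ± 5.99 and 479 ± 174. Laminin chains were higher for 6 of 7, LAMB2 being lower (camera adjusted p = 0.00963; adjusted p = 0.258 with an estimated correlation), with LAMC1 at 5515 ± 124 and 14216 ± 651. Interleukin receptor genes were higher for 9 of 14 and lower for IL17RB and IL27RA (camera adjusted p = 0.0250; adjusted p = 0.258 with an estimated correlation), with IL1R1 at 653 ± 24.7 and 1313 ± 180 and IL15RA at 23.9 ± 6.30 and 167 ± 33.4. S100A genes were 6 higher and 3 lower of 14, the 3 being S100A1, S100A4 and S100A13 (camera adjusted p = 0.0250; adjusted p = 0.498 with an estimated correlation), and tubulin genes, 4 higher and 8 lower of 16, were not called (0.205). In senescent replicates 1, 2 and 3 the median change was 1.32, 0.98 and 0.77 for SERPIN genes, 1.04, 1.09 and 1.29 for laminins, 0.75, 0.49 and 0.57 for interleukin receptors and 0.52, 0.40 and 0.06 for S100A genes. No median of the families and groups given here changed sign with TMM, quantile or library-total scaling.

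Senescent replicate 3 showed a smaller rise than replicates 1 and 2; its 3 tests were chosen after this had been seen. Growing-medium RNA mixed into the library would need the same share from raised and lowered genes, and the 98 genes raised at least 10 times in replicates 1 and 2 gave a median share of 60.9% (quartiles 48.5 and 71.7) where the 33 genes lowered as strongly gave 5.70% (2.82 and 9.09). A growing-medium library under the wrong label is argued against by all 131 of these genes, 100% of which lay outside the growing range on the side of replicates 1 and 2, and lower depth by its reads, 96.4% of their mean. No biological explanation was tested, since the design holds no factor within the group, and a weaker exposure remains as an untested hypothesis that may apply. ESR1 was highest (6308) and GREB1 lowest (267) in this library among those of its group.

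The rise of LCN2, S100A9, S100A8 and the other most raised genes, typical of neutrophils and inflamed epithelia, could come from other cells; the fibroblast test was chosen after the rise had been seen, as was the reading of the myeloid test over 4 genes. Fibroblast RNA is argued against by VIM, abundant in fibroblasts, which fell and stood at no more than 0.0610% of the rise of S100A9 in any senescent-medium library, although the matrix genes FBN1 and COL5A2 rose. Of 29 fibroblast markers written 16 were tested. The untested COL1A2, POSTN, FAP, THY1, PDGFRB, MMP2, PRRX1 and TWIST2 had means of at most 0.665 in both groups. Untested FBLN5 (0.347 and 14.8), CALD1 (4.29 and 12.1) and DCN (2.21 and 4.38) were higher in senescent-fibroblast medium. For myeloid cells, the summed rise of 15 marker genes was to stay under 1% of the rise of S100A9 if they were not the source, a bound that was not met, since it came to 1.35%, 2.50% and 4.09% in senescent replicates 1, 2 and 3. The sum held CORO1A, with 2282 ± 213 already in growing-fibroblast medium and no call (adjusted p = 0.0946), and 3 markers called higher: CD14 from 6.18 ± 1.38 to 117 ± 38.9 (adjusted p = 1.30e-06), ITGAM from 3.28 ± 0.761 to 65.0 ± 15.7 (1.59e-06) and ITGB2 from 89.7 ± 13.4 to 150 ± 32 (0.00535). Myeloid cells as the source are argued against by their abundant transcripts: PTPRC, LYZ, TYROBP and LAPTM5 rose together by at most 0.0695% of the rise of S100A9, with 0 reads of TYROBP in each senescent-medium library, so expression by the MCF7 cells themselves remains as an untested hypothesis, and the rise of CD14, ITGAM and ITGB2 stays open.

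The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split, 1 of the 10, gave 4376 higher and 3815 lower genes, and the highest of the other splits gave 0 of each with limma. Every other split puts libraries of both media into both groups, so a large difference between media adds to the spread within groups. Their counts therefore cannot tell how many calls chance would give.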
